A study of Homo sapiens with 4 samples.

How the data were processed

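The series holds RNA-seq of 4 libraries, 2 from IGROV1 wild-type (WT) cells and 2 from IGROV1 cisplatin-resistant (CR) cells, with groups and replicate numbers taken from the sample titles. Per the labels' protocols, poly(A) RNA was selected with oligo-dT beads and made into strand-marked libraries by dUTP incorporation. The deposited count table holds whole-number counts per Ensembl gene for each library, with 58051 genes and no normalization. Per the submitters' processing notes, STAR 2.5.1a, HTSeq and DESeq were used with genome build GRCh38.p7; the notes give no role or order. The annotation release and the strand setting of the counting are not given in the sources used here, so reads of a gene and an overlapping or antisense neighbour may not have been told apart. The second deposited table holds a normalized signal per gene and library. It equals the deposited counts divided by 1 factor per library, and the factors (0.9907, 0.9787, 1.0472 and 1.0234 for WT 1, WT 2, CR 1 and CR 2) match DESeq2's median-of-ratios size factors to a relative difference of at most 2.22e-16. This normalized signal was not used for tests. Its fold changes, on the log2(value + 1) scale, correlated with those of the fit at 0.983 across genes, with the same sign for all 2344 calls. Columns that could not be mapped to a sample numbered 0.

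Library totals ranged from 23886257 to 24727362 counts, and a total of 3 counts over a group was used as the counting floor. Without molecular identifiers, counting intervals (95%, exact binomial) and floors cover counting error only. Of 32907 genes with a count, 17304 passed edgeR's filterByExpr with the group and its minimum count of 10, and they held 99.87% of the counts; 13544 were protein coding. Gene symbols came from the table; rows without a symbol numbered 20988 and held 0.436% to 0.535% of the counts, and they stayed in the tests under their identifiers. Coordinates and biotypes came from GENCODE 29, which uses the same GRCh38 primary coordinates, and 57447 of the table's identifiers were found there.

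Analyses ran in R 4.3.3. The comparison, CR minus WT, was fitted to all 4 libraries with edgeR 4.0.16 (TMM factors, quasi-likelihood fit and test with robust estimation, group as the only term, two-sided), with Benjamini-Hochberg adjustment and a threshold of 0.05. Values are CPM with TMM-adjusted library sizes, given as mean ± SD of 2 libraries per group. Folds are ratios of summed counts scaled to the TMM-adjusted library sizes. Where a group had 0 counts the fold is a lower bound against the floor, and where it had 1 to 3 counts in total the ratio is given with its counting interval. Log2 fold changes come from the fit. Values given as SE are the absolute log2 fold change divided by the square root of the test's F statistic. They are back-calculated and carry no information beyond the test. An exact permutation test of 2 against 2 libraries cannot give a two-sided p under 0.333, so no such test is reported.

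The gene lists, the rule for named genes and the design were fixed before the data were examined. The 36 lists hold 887 symbols, of which 877 were found in the table. Lists with at least 4 tested members (35) were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation between genes of 0.01, two-sided, and Benjamini-Hochberg adjustment over the lists. Of the lists tested, 10 passed (4 higher, 6 lower). With the correlation estimated per list, 0 passed (camera, and 3 at an unadjusted p of 0.05). This setting leaves few degrees of freedom here, so hardly any list could pass. Correlation may add to the loss in some lists. Among the lists that passed, the estimate was above the preset for histones (0.43), NRF2 targets (0.11), immediate early genes (0.054) and epithelial genes (0.011). It was under the preset for the others. fry asks whether the members of a list change at all, while camera asks whether they move against the other genes. fry called 14 lists by direction and 30 in either direction. With 13.5% of all genes called, a fry call does not show a shift against other genes. Where a list held a gene with 0 counts in one group (4 lists), setting that gene to its bound moved 0 list medians.

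Genes were named by these rules: the 12 with the largest rise and the 12 with the largest fall among called protein-coding genes with a mean log2 CPM of at least 3 and both CR libraries on one side of both WT libraries; the 4 members of each list with the smallest adjusted p; the 3 largest gains and 3 largest losses in CPM among called genes; and the 6 most abundant genes on or off in each direction. This gave 164 genes, 127 of them called. Sex-linked transcripts that identify sex were not named. Other genes named in the text are said to have been chosen after their values were seen. Some genes that meet these rules are not reported here.

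The code was tested on simulated data: counts of the 17304 genes were drawn independently from their means, library sizes and dispersions, with 200 genes changed by known folds. Each gene had 1 dispersion for all 4 libraries, although the WT pair varied more (biological coefficient of variation 31.6%, against 9.51% in CR). Fewer genes were changed than were called in the data, so recovery in the data may differ. edgeR recovered 14 of 100 genes changed 2-fold and 75 of 100 changed 4-fold with 8 false calls, DESeq2 1.42.0 recovered 25 and 78 with 22, and limma-voom 13 and 75 with 8. camera recovered 5 of 5 simulated lists of 25 genes shifted by 0.5 log2 units with 1 false call among 30 unchanged lists, and 3 of 3 overlapping windows of 50 genes in 1 block shifted by 0.7 with 0 false calls among 686. The simulated genes were independent, so this does not show how often camera calls lists of co-regulated or neighbouring genes falsely.

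The alternatives fixed with the design were median-of-ratios, upper quartile and library-size scaling, no or a stricter low-count filter (1 CPM in 2 libraries and 50 counts in total), DESeq2, limma-voom, edgeR without robust estimation, the replicate number as a block, leaving out each library in turn, a test against a fold of 2, an estimated correlation, fry, a prior count of 0.5, other size rules for on and off genes and other window sizes. GC content and length offsets, a crossed pairing, and the list counts without each WT library were added after seeing the data. Chromosomal regions were tested with camera on windows of 50 neighbouring genes in steps of 25, with 100 random gene orders as the null.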

Results

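Polyadenylated RNA of IGROV1, an established human ovarian carcinoma line, was sequenced as stranded libraries from the wild-type (WT) line and from a cisplatin-resistant (CR) line derived from it. The CR line came from repeated short exposures to rising concentrations of cisplatin, a platinum drug that crosslinks DNA, each followed by recovery in drug-free medium. Both lines were collected during log growth without drug. The comparison thus asks how the drug-free transcriptome of the selected line differs from that of its parent. The labels name 2 biological replicates per group and 4 libraries in all. The libraries held 23886257 and 24264458 counts (WT replicates 1 and 2) and 24727362 and 24008899 counts (CR replicates 1 and 2). All replicates come from 1 resistant line and 1 parent line, so the tests measure the spread between cultures of these lines and not between independent selections.

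The CR cells differed from the WT cells by changes that ranged from shifts in abundant transcripts to complete on and off states. Among the genes that rose furthest were MPDZ, a tight junction scaffold protein, PLAGL1, an imprinted zinc finger transcription factor, and SLC1A1, a glutamate and cysteine transporter. Among those that fell furthest were MYL9, a myosin light chain of contractile cells, INA, a neuronal intermediate filament, and HS6ST2, a heparan sulfate sulfotransferase. Of 17304 genes tested, 942 were higher and 1402 lower in CR (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p at most 0.05), which is 13.5% of the genes tested. Of these calls 873 and 1282 changed at least 2-fold, and 353 and 691 at least 8-fold. A test against a fold change of 2 itself called 1231 genes. The counts rest on few libraries: there were 3647 higher and 3715 lower calls without WT replicate 1, and 3882 and 4004 without WT replicate 2. They were 595 and 911 without CR replicate 1, and 565 and 865 without CR replicate 2. All 2344 calls kept their sign in each of these fits, which was nearly fixed in advance. In all 2344, both CR libraries lay on one side of both WT libraries in CPM. With 1 library left in a group, the spread is taken from the other pair alone. Calls therefore rose over all genes without a WT library and dropped without a CR library, and counts of list members from such fits follow this.

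The WT libraries differed from each other more than the CR libraries did. Across the tested genes, log2 CPM (counts scaled to the library size) correlated at 0.97 between the WT replicates and at 0.991 between the CR replicates, and at 0.885 to 0.893 between groups (across genes, which are not independent replicates). The typical log2 ratio between replicates, as a median absolute deviation, was 0.645 in WT and 0.246 in CR. Each pair differed by far more than counting noise, with a chi-square of 89.9 times its degrees of freedom in WT and 14.4 times in CR, so no library was counted as a copy of another. Transcripts encoded in mitochondrial DNA took 10.3% and 6.68% of the counts in WT and 8.81% and 10.1% in CR.

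Many of the genes with the largest changes had close to 0 counts in one of the groups. MPDZ (chromosome 9, 13105704 to 13279590) had 0 counts in WT and 41.6 ± 4.83 CPM in CR (mean ± SD, n = 2 libraries per group here and throughout), at least 655-fold higher with 3 counts over the group as the floor. PLAGL1 (chromosome 6, 143940300 to 144064599) had 1 count in WT and 83.3 ± 6.65 CPM in CR, a ratio of 3937 with a 95% counting interval of 706 to 155545. SLC1A1, with 2 counts in WT, reached 77.5 ± 0.713 CPM (ratio 1830.4, interval 506 to 15119.9). CDCA7L and SLC46A3 each had 1 count in WT and 40.2 ± 1.8 and 17.6 ± 2.82 CPM in CR. SYCP2, a protein of the meiotic chromosome axis, rose from 0.38 ± 0.114 to 77.4 ± 10.2 CPM, and MNS1, known from meiotic cells and cilia, from 0.0847 ± 0.00136 to 22.9 ± 2.61 CPM. The basement membrane collagen COL4A5, the transcription factor RUNX3, the pantetheinase VNN1, the neuritin gene NRN1 and the cancer-testis antigen SSX5 completed the 12, rising 120.0-fold to 343-fold. SSX5 belongs to a family of near-identical copies, and reads could have been split among them.

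In the other direction, NRSN2 (chromosome 20, 346782 to 359660) fell from 76.6 ± 14.7 CPM to 0 counts, at least 1265-fold lower. TUB and HS6ST2 fell from 63.1 ± 14.1 and 52.5 ± 31.3 CPM to 0 counts, at least 1044-fold and 872-fold lower. MYL9 (chromosome 20, 36541484 to 36551447) fell from 697 ± 79.4 to 0.0802 ± 0.0555 CPM, 8648-fold lower (log2 fold change -12.99, SE 0.37; edgeR adjusted p = 9.21e-05). INA fell from 140.0 ± 5.72 CPM to 1 count (ratio 6943, interval 1246 to 274277) and BEX3 from 106 ± 5.24 CPM to 1 count. The remaining 6 of the 12, B3GALNT1, ACOT2, GABRQ, TUNAR, ZNF100 and ACSF2, had 16.2 to 20.6 CPM in WT and 0 counts in CR, at least 268-fold to 342-fold lower. Intervals and floors cover counting error only.

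**Figure D1:**
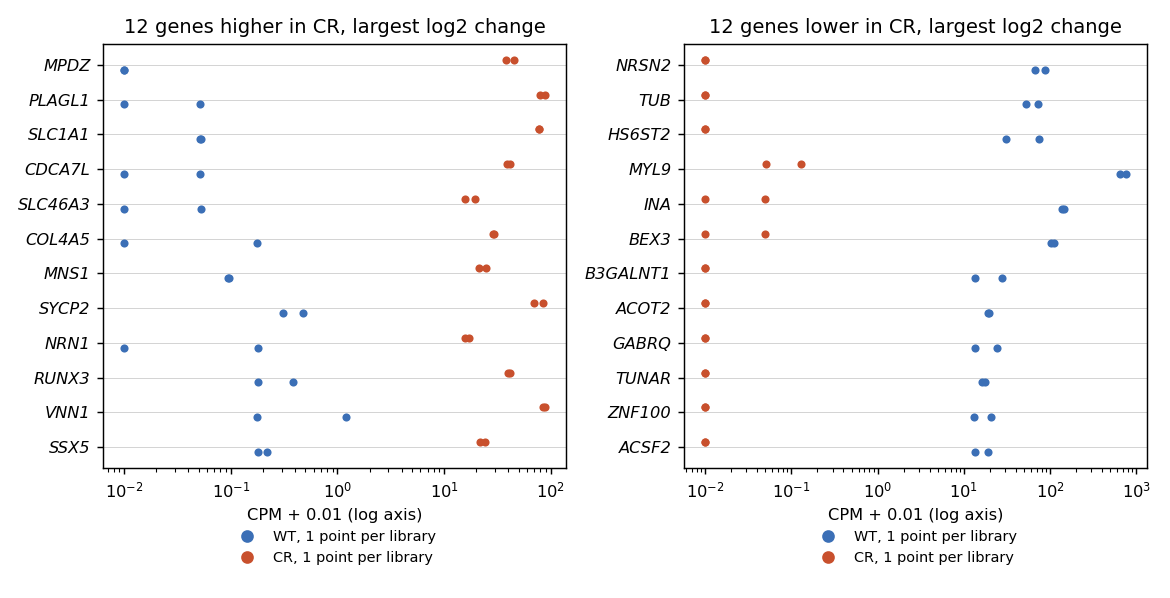
CPM with 0.01 added, on a log axis, of the 12 named genes with the largest rise (left) and the largest fall (right) in CR, 1 point per library and 2 libraries per group. Points at 0.01 are libraries with 0 counts; in each gene both CR points lie on the same side of both WT points.

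By a rule of size with no test, 57 genes were off in CR (at least 5 CPM in both WT libraries and at most 3 counts over both CR libraries) and 26 were on in CR by the mirrored rule. Of these, 52 and 22 were annotated as protein coding. Between the replicates of a group, a single-library form of the rule was used (at least 5 CPM in 1 library and at most 3 counts in the other). It found 0 genes in each of the 4 possible directions. The most abundant genes off in CR were INA, BEX3, NRSN2, TUB, HS6ST2 and CCL2. Those on in CR were PLAGL1, SLC1A1, MPDZ, CDCA7L, SLC46A3 and ARMCX5, the last with 0 counts in WT and 15.4 ± 1.21 CPM in CR.

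Among genes past the threshold, the largest gains in CPM were in APLP2, a relative of the amyloid precursor protein, SPP1, which encodes the secreted matrix protein osteopontin, and FTL, the ferritin light chain. APLP2 rose from 977 ± 90.1 to 2862 ± 164 CPM (log2 fold change 1.55, SE 0.16; edgeR adjusted p = 0.00133). SPP1 rose from 132 ± 94.9 to 1539 ± 29.5 CPM and FTL from 1451 ± 318 to 2776 ± 136 CPM. SPP1 was not called when no low-count filter was applied (edgeR adjusted p = 0.181). The largest losses were in the chaperone HSP90AB1, from 4375 ± 637 to 1548 ± 12.03 CPM, the cytoskeletal actin ACTB, from 5799.9 ± 1175 to 3483 ± 175 CPM, and the simple epithelial keratin KRT8, from 1622 ± 195 to 628 ± 10.9 CPM. ACTB was close to the threshold (edgeR adjusted p = 0.0432) and was not called with upper quartile factors (0.0796), library size alone (0.0518), a stricter low-count filter (0.0579) or without CR replicate 1 (0.0809) or 2 (0.105).

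Several drug efflux and cation transporters rose in CR, and most members of their list did not pass. ABCB1 (P-glycoprotein; chromosome 7, 87503633 to 87713323) rose from 6.05 ± 3.95 to 209.5 ± 17.2 CPM, 34.5-fold (log2 fold change 5.11, SE 0.48; edgeR adjusted p = 0.000858). ABCC2, the canalicular multidrug resistance protein (chromosome 10, 99782640 to 99852594), rose from 15.6 ± 4.75 to 231 ± 13.9 CPM, 14.8-fold (edgeR adjusted p = 0.000342). SLC47A1, a proton-coupled cation exporter, rose from 0.658 ± 0.16 to 16.6 ± 1.76 CPM, and SLC22A3, an organic cation transporter, from 0 counts to 6.92 ± 0.161 CPM, at least 109-fold higher. The copper exporter ATP7B (52.2 ± 13.4 to 264 ± 42.0 CPM) also rose and SLC22A2 (8.21 ± 1.43 to 2.26 ± 0.214 CPM) fell; both were named after their values were seen. Of 24 measured members of the list of platinum and copper transport and drug efflux, 5 rose, 1 fell and 18 did not pass, and the same 5 and 1 passed adjusted over the list alone. The list was higher in CR as a set (camera, adjusted p = 0.037; adjusted p = 0.496 with an estimated correlation). That call was lost without WT replicate 1 (camera adjusted p = 0.106) and without WT replicate 2 (0.0509), where 10 and 10 members rose and 3 and 5 fell. With CR replicate 1 or 2 left out, the member that fell was not called.

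Targets of NRF2, the transcription factor of the oxidative stress response, were higher as a set (camera, adjusted p = 0.0128; adjusted p = 0.628 with an estimated correlation). The estimate was 0.11, above the preset 0.01, so the set call rests on the preset. Of 24 measured members 6 rose and 1 fell, and 7 and 1 did so adjusted over the list alone. NQO1, a quinone reductase, rose from 294 ± 94.6 to 1581 ± 78.6 CPM and HMOX1, haem oxygenase 1, from 27.0 ± 7.08 to 99.5 ± 0.607 CPM. ABCC2 and FTL, given above, belong to the same list, while AKR1C3, an aldo-keto reductase, fell from 37.5 ± 1.71 to 11.5 ± 0.906 CPM. The list's camera call was lost without WT replicate 2, where its median log2 fold change was 0.35 (0.48 in the full fit). By fry, which tests against no change and not against other genes, the list did not pass (adjusted p = 0.0622). The members that rose numbered 16 and 12, and those that fell 2 and 4, without WT replicates 1 and 2. With GC content and length offsets 13 rose.

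Genes of glutathione synthesis and conjugation did not pass as a set against the other genes (camera, adjusted p = 0.367). Against no change they were lower (fry, adjusted p = 0.0382). Of 24 members 1 was higher and 3 lower, or 5 and 4 adjusted over the list alone. GSTM2 fell from 16.9 ± 0.331 to 0.704 ± 0.186 CPM and GSTM4 from 137 ± 9.06 to 42.8 ± 0.561 CPM. MGST1, a membrane-bound transferase, fell from 3.68 ± 0.18 CPM to 0 counts, at least 60.9-fold lower. GGT1 rose from 34.9 ± 14.8 to 82.7 ± 1.55 CPM, a call lost without CR replicate 1 or 2 (edgeR adjusted p = 0.0783 and 0.123). GSTM2, GSTM4 and GGT1 have close paralogs with which reads could have been shared. The list had 8 higher and 6 lower members without WT replicate 1 and 7 and 11 without WT replicate 2. It had 5 and 4 with no low-count filter and 7 and 4 with GC content and length offsets. The metallothioneins had only 2 measured members and no set test: MT2A had 10.7 ± 6.31 CPM in WT and 24.2 ± 6.08 in CR and MT1X had 1.48 ± 0.144 and 1.499 ± 0.599, neither past the threshold (edgeR, 1 at an unadjusted p of 0.05; DESeq2 called 1, limma-voom 0). With either WT library left out, 1 of them was higher.

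**Figure D2:**
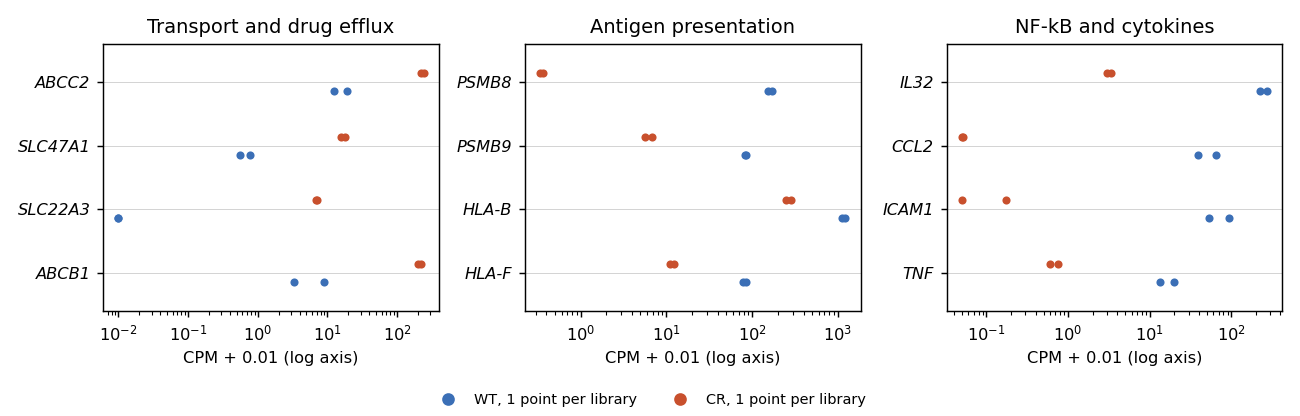
CPM with 0.01 added, on a log axis, of the 4 members with the smallest adjusted p in 3 lists, 1 point per library and 2 libraries per group. The transporter genes lie higher in both CR libraries, and the antigen presentation and cytokine genes lower.

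DNA repair lists showed few calls. Of 33 genes of nucleotide excision repair, the pathway that removes platinum adducts, 0 passed (edgeR; 3 at an unadjusted p of 0.05; DESeq2 0, limma-voom 0). The nearest were ERCC2 (69.3 ± 12.6 CPM in WT, 43.5 ± 1.82 in CR), CDK7 (44.4 ± 0.533 and 29.98 ± 4.23), XPC (54.5 ± 7.72 and 79.6 ± 11.4) and LIG3 (34.4 ± 1.69 and 48.9 ± 6.17). Of 38 genes of homologous recombination and the Fanconi anaemia pathway only FANCI passed, rising from 170.0 ± 47.9 to 338 ± 16.9 CPM, with 0 adjusted over the list alone. In mismatch repair, 2 of 14 genes passed: MSH3 rose from 13.2 ± 0.836 to 34.8 ± 0.589 CPM and PCNA, the replication clamp, fell from 293 ± 33.0 to 168 ± 7.69 CPM. Of 14 translesion synthesis genes 0 passed (edgeR; 0 at an unadjusted p of 0.05; DESeq2 0, limma-voom 0). None of the 4 lists passed as a set (camera, adjusted p = 0.734, 0.689, 0.912 and 0.734). FANCI, MSH3 and PCNA were not called without CR replicate 1 (edgeR adjusted p = 0.144, 0.0765 and 0.387) or 2 (0.0748, 0.0633 and 0.251). Calls appeared in these lists when WT replicate 1 or 2 was left out, as they did over all genes, since the spread then came from the tighter CR pair. Median log2 fold changes in those 2 fits were -0.1 and -0.02 for nucleotide excision repair and 0.02 and 0.15 for homologous recombination. They were -0.06 and 0.09 for mismatch repair and -0.16 and 0.21 for translesion synthesis. A test on counts simulated at this depth recovered 14 of 100 genes changed 2-fold and 75 of 100 changed 4-fold. The simulation gave both groups the same spread and changed fewer genes than were called in the data. It therefore does not give the recovery in these data, and changes of 2-fold or less may have been missed.

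Targets of p53, which responds to DNA damage, were not shifted as a set (camera, adjusted p = 0.214): 2 of 25 rose and 0 fell. Without WT replicate 1 or 2 the counts were 8 and 6 or 14 and 3, and with GC content and length offsets 7 and 0. The 2 were TP53INP1, from 2.81 ± 1.12 to 12.4 ± 2.58 CPM, and GDF15, from 32.5 ± 12.1 to 97.1 ± 1.51 CPM. Among apoptosis-promoting genes 4 of 24 fell and 0 rose (camera, adjusted p = 0.592): CASP10 (8.36 ± 2.68 to 1.16 ± 0.564 CPM), the death ligand TNFSF10 (1.84 ± 0.179 to 0.0818 ± 0.116), BIK (12.9 ± 2.60 to 5.19 ± 0.356) and CASP8 (61.6 ± 5.21 to 32.0 ± 2.04). Leaving out WT replicate 1 gave 4 higher and 11 lower, leaving out WT replicate 2 gave 8 and 7, and leaving out either CR library gave 0 and 2. Of 15 apoptosis-restraining genes only BIRC3 passed, falling from 128 ± 1.51 to 75.2 ± 5.12 CPM (camera for the list, adjusted p = 0.819). Adjusted over the list alone 0 passed, and 0 passed with library size alone or with the replicate block. The list's median log2 fold change was -0.15 and 0.1 without WT replicate 1 and 2. Without CR replicate 1 or 2, BIK (edgeR adjusted p = 0.307 and 0.216), CASP8 (0.326 and 0.471) and BIRC3 (0.587 and 0.399) were not called.

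Most genes of antigen presentation were lower in CR. PSMB8, a subunit of the immunoproteasome (chromosome 6, 32840717 to 32844703), fell from 162 ± 10.5 to 0.343 ± 0.022 CPM, 471-fold lower (log2 fold change -8.86, SE 0.30; edgeR adjusted p = 9.28e-05). Its partner PSMB9 fell from 83.4 ± 1.27 to 6.24 ± 0.890 CPM. The class I genes HLA-B and HLA-F fell from 1170.0 ± 86.6 to 266 ± 21.6 CPM and from 81.9 ± 5.84 to 11.6 ± 0.920 CPM. Of 20 members 14 fell and 1 rose, and 16 and 1 did so adjusted over the list alone. The 1 that rose was HLA-DMB, named after its values were seen (9.42 ± 7.76 to 100.1 ± 8.34 CPM), and with no low-count filter 0 members rose. The HLA genes are highly polymorphic and share sequence, which makes their counts uncertain. The median log2 fold change of the list was -1.28 (camera, adjusted p = 1.29e-08; adjusted p = 0.37 with an estimated correlation).

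Part of the interferon-stimulated genes and of the inflammatory cytokine genes fell as well. Of 35 interferon-stimulated genes 10 fell and 0 rose, with 16 lower adjusted over the list alone (median log2 fold change -0.75; camera, adjusted p = 2.36e-06; adjusted p = 0.37 with an estimated correlation). IFI27 fell from 95.1 ± 7.52 to 4.57 ± 1.57 CPM, the RNA sensor IFIH1 from 30.9 ± 5.88 to 4.64 ± 0.260 CPM, and XAF1 from 4.18 ± 1.55 CPM to 0 counts, at least 69.3-fold lower. SAMD9L fell from 5.50 ± 0.810 CPM to 3 counts (ratio 91.0, interval 30.8 to 444). Of 21 genes of NF-kB signalling and inflammatory cytokines 10 fell and 0 rose, with 13 lower adjusted over the list alone (median -1.48; camera, adjusted p = 3.07e-08; adjusted p = 0.37 with an estimated correlation). IL32 fell from 249 ± 36.8 to 3.17 ± 0.253 CPM, the chemokine CCL2 from 52.3 ± 18.6 CPM to 2 counts (ratio 1299.6, interval 359 to 10737), the adhesion molecule ICAM1 from 72.9 ± 27.4 to 0.102 ± 0.0875 CPM, and TNF from 16.6 ± 4.70 to 0.667 ± 0.0984 CPM. Leaving out WT replicate 1 or 2, the interferon list had 25 and 20 lower members with 1 and 1 higher, and the NF-kB list 16 and 17 lower with 1 and 0 higher. Markers of leukocytes, which express many of these genes, had 5 of 16 genes above the count filter, with 1 higher and 2 lower in CR (camera, adjusted p = 0.597). ITGAM fell from 10.2 ± 1.78 to 1.03 ± 0.334 CPM and CORO1A from 7.94 ± 2.04 to 0.688 ± 0.241 CPM, LAPTM5 rose from 0.401 ± 0.143 to 5.85 ± 0.173 CPM, and FCER1G had 0.404 ± 0.216 CPM in WT and 0.284 ± 0.177 in CR. Fibroblast and mesothelial markers were lower in CR as well (camera, adjusted p = 0.0304 and 0.0128; adjusted p = 0.496 with an estimated correlation for both). The fibroblast call was lost without WT replicate 1 (camera adjusted p = 0.0879) or 2 (0.0745).

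Epithelial genes moved both ways, mostly down. KRT7, a keratin of simple epithelia, fell from 395 ± 203 to 5.02 ± 0.332 CPM, 78.4-fold, the membrane protease ST14 from 46.3 ± 8.53 to 1.29 ± 0.0818 CPM, and the junction protein TJP3 from 27.5 ± 11.9 to 6.21 ± 0.452 CPM, while KRT8 is given above. Of 23 members 9 fell and 3 rose, 11 and 4 adjusted over the list alone (camera, adjusted p = 0.0371; adjusted p = 0.496 with an estimated correlation). The 3 that rose, named after their values were seen, were the adhesion genes CDH1 (79.7 ± 39.7 to 244 ± 19.6 CPM) and EPCAM (116 ± 3.95 to 209 ± 20.8) and MAL2 (72.5 ± 14.8 to 154 ± 12.9). The list was not called without WT replicate 1 (camera adjusted p = 0.113) or 2 (0.0687), nor with a stricter low-count filter (0.106). Its members numbered 7 higher and 14 lower, and 5 and 13, without WT replicates 1 and 2. Without CR replicates 1 and 2 they numbered 1 higher and 7 lower, and 1 and 6.

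Mesenchymal genes were lower in part: 5 of 18 fell and 2 rose (camera, adjusted p = 0.365, and lower against no change by fry, adjusted p = 0.0259). TAGLN, an actin-binding protein, fell from 581 ± 97.1 to 13.3 ± 0.740 CPM and the receptor AXL from 11.3 ± 1.08 to 0.831 ± 0.387 CPM. SPARC had 23.98 ± 25.7 CPM in WT and 0.101 ± 0.0266 in CR, with a WT spread as large as its mean; it was not called by limma-voom (adjusted p = 0.0597) or by edgeR without a low-count filter (adjusted p = 0.247). Extracellular matrix genes also split, with 8 of 26 lower and 4 higher (camera, adjusted p = 0.689; the list's median log2 fold change of 0.28 and mean of -0.40 differ in sign, and the median was 0.44 without WT replicate 1 and 0.00 without WT replicate 2). LAMB3 fell from 185 ± 34.1 to 26.7 ± 2.49 CPM, COL1A1 from 44.3 ± 18.2 to 1.38 ± 0.369 CPM, and COL4A1 from 929 ± 186 to 243 ± 12.6 CPM, while COL4A5 rose. When WT replicate 1 or 2 was left out, 12 and 7 matrix genes rose and 10 and 10 fell, and 5 and 4 mesenchymal genes rose and 7 and 8 fell.

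Markers of other cell types were examined in the same libraries. Fibroblast markers were lower (0 of 5 higher, 2 lower; camera, adjusted p = 0.0304; adjusted p = 0.496 with an estimated correlation), with FBLN1 from 96.7 ± 23.0 to 0.161 ± 0.00309 CPM and COL1A1 as above, while THY1 (11.9 ± 2.74 and 6.60 ± 0.188 CPM) and PDGFRA (0.211 ± 0.0565 and 0.546 ± 0.096) did not pass. This call was lost without WT replicate 1 (camera adjusted p = 0.0879, 4 lower) or 2 (0.0745, 3 lower). Mesothelial markers were lower (3 of 4 lower, 0 higher; camera, adjusted p = 0.0128; adjusted p = 0.496 with an estimated correlation): MSLN fell from 191 ± 71.0 to 45.9 ± 1.03 CPM, LRRN4 from 6.07 ± 1.37 to 1.49 ± 0.1997 and KLK11 from 149.6 ± 52.6 to 57.5 ± 1.99, and UPK3B had 486 ± 7.98 and 352 ± 10.3 CPM. LRRN4 was not called without CR replicate 2 (edgeR adjusted p = 0.115). Of 6 endothelial markers CDH5 fell from 44.0 ± 3.31 to 0.989 ± 0.0475 CPM and PECAM1 rose from 0.232 ± 0.146 to 3.53 ± 0.360 CPM, with VWF at 31.9 ± 9.49 and 27.1 ± 2.25 CPM and CLDN5 at 0.255 ± 0.064 and 0.866 ± 0.183 CPM (camera, adjusted p = 0.734). Of 10 ovarian and Mullerian epithelial markers 4 fell and 2 rose (camera, adjusted p = 0.599): besides KRT7 and MSLN, MUC16, which carries the antigen CA-125, fell from 36.0 ± 19.3 to 5.70 ± 2.80 CPM, and the developmental factor PAX2 rose from 2.21 ± 0.994 to 46.2 ± 0.998 CPM. This list had 5 higher members without WT replicate 1, and the endothelial list 4 higher and 2 lower.

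Stem-like and aldehyde dehydrogenase genes changed in both directions, with 6 of 22 higher and 5 lower (camera, adjusted p = 0.689). ALDH1A1, which oxidises retinaldehyde, rose from 81.0 ± 24.5 to 507 ± 1.37 CPM, the folate enzyme ALDH1L1 from 0.528 ± 0.141 to 22.4 ± 1.71 CPM and the RNA-binding protein LIN28A from 2.97 ± 0.0476 to 26.5 ± 1.56 CPM. ALDH2, the mitochondrial acetaldehyde dehydrogenase, fell from 64.4 ± 13.6 to 0.686 ± 0.0439 CPM. The list's median was -0.02 and its mean 0.31, and the sign of the median changed with the scaling. With WT replicate 1 or 2 left out, 10 and 8 rose and 8 and 8 fell. The members that fell numbered 2 and 3 without CR replicate 1 or 2.

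Immediate early genes, which respond within minutes to growth factors and stress, were higher (8 of 24 higher, 1 lower; 11 and 2 adjusted over the list alone; camera, adjusted p = 0.00223; adjusted p = 0.496 with an estimated correlation). IER3 rose from 1.70 ± 0.506 to 22.4 ± 1.51 CPM, DUSP6 from 14.8 ± 2.51 to 68.9 ± 2.26, FOSL1 from 15.9 ± 2.80 to 59.3 ± 2.66 and EGR2 from 2 counts to 3.47 ± 0.447 CPM (ratio 81.9, interval 22.3 to 682). The counts were 14 higher and 3 lower without either WT library, and 6 or 5 higher and 0 lower without CR replicate 1 or 2. Replication-dependent histone genes, whose main transcripts carry no poly(A) tail and which can mark the RNA selection of a library, were higher (4 of 8 higher, 0 lower; 6 adjusted over the list alone; camera, adjusted p = 0.00127; adjusted p = 0.602 with an estimated correlation). The estimate for the histone list was 0.43, above the preset 0.01, so this set call rests on the preset. HIST1H2BK rose from 4.35 ± 0.579 to 16.2 ± 0.139 CPM, HIST1H2AC from 2.33 ± 0.0973 to 7.62 ± 0.881, HIST1H1C from 7.27 ± 1.22 to 17.8 ± 0.630 and HIST1H2BC from 1.40 ± 0.0974 to 4.53 ± 0.6002. The last 3 were not called without CR replicate 1 (edgeR adjusted p = 0.144, 0.204 and 0.0962) or 2 (0.0623, 0.149 and 0.246), and histone reads could be shared among near-identical copies. In this list 7 members rose without WT replicate 1 and 1 without either CR library.

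**Figure D3:**
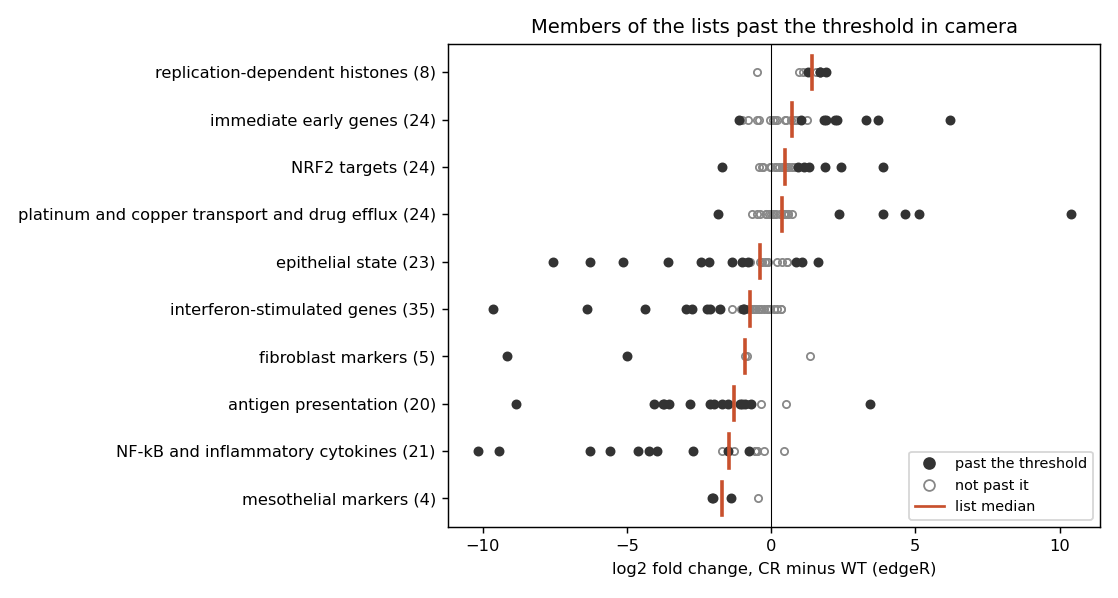
Log2 fold change (CR minus WT, edgeR) of each measured member of the 10 lists past the threshold in camera with its preset correlation, with filled points for genes past the threshold and a bar at the list median; the number of members is in parentheses. Medians range from -1.70 in the 4 mesothelial markers to 1.42 in the 8 histone genes, and a gene with 0 counts in one group is drawn at its fitted value, which is not a bound.

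Growth factor and signalling genes changed in single members more than as sets. Among receptor tyrosine kinases and ligands 5 of 33 rose and 5 fell (camera, adjusted p = 0.689; median 0.17, mean -0.04). EREG, a ligand of the epidermal growth factor receptor, rose from 3.18 ± 1.96 to 98.3 ± 4.77 CPM and PDGFB from 7.65 ± 0.512 to 54.7 ± 2.38 CPM, while MERTK fell from 13.2 ± 2.06 to 0.182 ± 0.0320 CPM. Among TGF-beta and BMP responders 7 of 24 fell and 2 rose (camera, adjusted p = 0.579): LTBP1 fell from 87.6 ± 38.9 to 0.1404 ± 0.0829 CPM, BMP4 from 72.1 ± 7.15 to 3.91 ± 0.0963 and TGFB1 from 27.0 ± 11.01 to 1.74 ± 0.433, and ID2 rose from 8.73 ± 2.05 to 63.6 ± 1.99. Among YAP and TAZ targets 6 of 24 fell and 2 rose (camera, adjusted p = 0.273), with ANKRD1 from 218 ± 73.7 to 7.25 ± 0.395 CPM, CTGF from 5.93 ± 2.87 to 0.445 ± 0.123 and F3 from 60.4 ± 16.6 to 17.4 ± 1.13. Among Wnt pathway genes and targets 4 of 22 rose and 4 fell (camera, adjusted p = 0.734). DKK3 fell from 24.5 ± 4.97 to 0.1399 ± 0.13998 CPM and WNT11 from 1.63 ± 0.00378 CPM to 2 counts, and FZD8 rose from 5.53 ± 0.418 to 35.02 ± 0.2999 CPM and SFRP1 from 0.127 ± 0.00204 to 1.82 ± 0.149. Without WT replicates 1 and 2 the higher and lower counts were 11 and 9, then 12 and 7, for the receptor list, 8 and 10, then 6 and 8, for the TGF-beta list, 5 and 13, then 8 and 10, for the YAP list, and 6 and 5, then 10 and 6, for the Wnt list. Without CR replicate 1 or 2 the Wnt list had 2 higher members, and with GC content and length offsets 9 receptor and ligand, 7 Wnt and 5 TGF-beta list members rose.

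Metabolic and growth lists did not pass as sets in camera. Of 32 genes of hypoxia and glycolysis 6 fell and 1 rose (camera, adjusted p = 0.273). With GC content and length offsets 8 fell and 4 rose, and with no low-count filter 9 and 3. EGLN3 fell from 16.1 ± 1.66 to 4.03 ± 0.322 CPM, P4HA2 from 152 ± 10.3 to 58.3 ± 0.739 and LDHA from 1831 ± 115 to 1093 ± 62.5, and NDRG1 rose from 62.5 ± 21.2 to 190.3 ± 13.1. Of 32 genes of cholesterol and fatty acid synthesis 3 rose and 1 fell (camera, adjusted p = 0.0725). In camera the list passed with a stricter low-count filter (adjusted p = 0.0482) and with GC content and length offsets (0.0339). Against no change it passed as well (fry, adjusted p = 0.0452). With those offsets 8 rose, with no low-count filter 8 and with the replicate block 6, and 1 fell in each. SQLE rose from 140.2 ± 3.50 to 302 ± 20.01 CPM and SCD from 504 ± 155 to 1163 ± 50.7, and the fatty acid elongase ELOVL6 fell from 68.6 ± 15.9 to 1.04 ± 0.494. In the unfolded protein and integrated stress response 1 of 28 rose and 2 fell (camera, adjusted p = 0.734), with PHGDH, the first enzyme of serine synthesis, from 209 ± 45.0 to 0.364 ± 0.121 CPM (574-fold lower), SHMT2 from 282 ± 34.0 to 172 ± 7.25 and VLDLR from 85.8 ± 10.6 to 276 ± 11.3. Of 36 proliferation genes 3 fell and 1 rose (camera, adjusted p = 0.228, and lower against no change by fry, adjusted p = 0.036). TPX2 fell from 354 ± 16.6 to 163 ± 1.56 CPM, CENPE from 131 ± 4.41 to 66.3 ± 1.90 and PCNA as above, and MCM2 rose from 121 ± 2.21 to 199 ± 10.2. Without CR replicate 1 or 2, LDHA (edgeR adjusted p = 0.213 and 0.128), SHMT2 (0.508 and 0.356), TPX2 (0.0621 and 0.0637), CENPE (0.276 and 0.231) and MCM2 (0.557 and 0.357) were not called, nor was SQLE without CR replicate 2 (0.0840). Leaving out WT replicate 1 or 2, 12 and 15 sterol and fatty acid genes rose and 4 and 3 fell, 7 and 6 glycolytic genes rose and 9 and 13 fell, 2 and 5 proliferation genes rose and 10 and 12 fell. In the same fits 5 and 3 stress response genes rose and 4 and 6 fell. When CR replicate 1 or 2 was left out, 2 and 3 glycolytic and 0 and 0 proliferation genes fell.

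Of 38 nuclear-encoded genes of oxidative phosphorylation, COX6B1 rose from 114 ± 26.2 to 429.7 ± 40.6 CPM and UQCRB fell from 150.3 ± 3.88 to 60.3 ± 7.55 CPM, a call lost without CR replicate 1 (edgeR adjusted p = 0.0953). As a set these genes did not pass (camera, adjusted p = 0.938; median -0.08, mean 0.03), with 11 higher and 5 lower or 6 and 7 without WT replicate 1 or 2. The median was 0.05 without WT replicate 1 and 0.04 without CR replicate 1. Of 13 mitochondrially encoded transcripts 0 passed (edgeR; 0 at an unadjusted p of 0.05; DESeq2 0, limma-voom 0; camera, adjusted p = 0.734), with MT-CO1 at 14202 ± 3329 CPM in WT and 19247 ± 1169.8 in CR. Leaving out WT replicate 1 made 7 of them higher, and leaving out WT replicate 2 made 3 lower. Of 49 ribosomal protein genes 0 passed (edgeR; 4 at an unadjusted p of 0.05; DESeq2 0, limma-voom 0; camera, adjusted p = 0.51), with RPS19 at 578 ± 66.6 and 855 ± 52.4 CPM and RPS27A at 629 ± 48.2 and 448 ± 48.8 CPM. The counts were 3 higher and 1 lower without WT replicate 1, and 3 and 15 without WT replicate 2.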

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

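Numbers of higher, lower and at least 2-fold changed genes stayed within 1.5 times of 942, 1402 and 2155 under the other scalings and the stricter filter. They did so with DESeq2, limma-voom and non-robust estimation as well. No call changed sign in any fit. This could hardly have come out otherwise, since the libraries of the groups did not overlap in any called gene. Without a low-count filter 1454 genes were higher, and the test against 2-fold called 1231. Leaving out 1 library gave 565 to 3882 higher, 865 to 4004 lower and 1427 to 3609 genes changed at least 2-fold; the lone library is then assumed to vary like the other group, so the counts follow the tight CR pair or the wide WT pair. The replicate number as a block gave 1258 higher and 1517 lower genes. Deviations of same-numbered libraries correlated weakly and negatively (-0.174 across genes, which are not independent replicates). The labels name no shared day, so whether the numbers pair the samples is not known. The crossed pairing, chosen after seeing the data, gave 1671 higher and 1803 lower genes. Offsets for GC content and length, also chosen afterwards, gave 1857 and 1872. Of 127 called named genes, 17 and 18 lost the call without CR replicate 1 and 2, 3 with library size alone and 3 with the block; 27 and 26 uncalled ones gained it without WT replicate 1 and 2. Lists past the threshold numbered 10 in the fit, 0 with an estimated correlation, 30 by fry in either direction, and 6 to 10 without 1 library. fry's directional test called the endothelial markers downward (adjusted p = 0.0265), against their median of 0.10 and camera's upward, uncalled direction; 4 more uncalled lists passed (glutathione 0.0382, mesenchymal 0.0259, proliferation 0.036, cholesterol 0.0452) and the NRF2 targets did not (0.0622); the cause was not tested. Genes off and on in CR numbered 125 and 52 at a minimum of 2 CPM and 36 and 12 at 10 CPM, by construction of the rule. Windows with shifted expression were 3.95% with 50 genes, 4.3% with 30 and 2.88% with 100. The median log2 fold change of all genes lay within 0.048 of 0 in every fit. Depth limits genes with few counts, for which ratios have wide counting intervals.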

Other observations

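The gene families, STAG3 and PEG10, the chromosome X counts, the 3 regions described and the leukocyte test were chosen only after the results were seen. Clustered protocadherins, neuronal adhesion proteins encoded side by side on chromosome 5, were higher in CR in 9 of 13 tested members and lower in 1 (edgeR; no set test was made), with a median log2 fold change of 2.93. PCDHAC2 rose from 0.0209 ± 0.0296 to 10.8 ± 3.59 CPM (SD, n = 2) and PCDHB13 from 0.486 ± 0.082 to 5.62 ± 0.834 CPM, while PCDHGC3 fell from 7.75 ± 2.60 to 0.342 ± 0.136 CPM. Without CR replicate 1, 5 members were higher. Most of the other members that rose were weak in both groups, such as PCDHGA11 (0.0419 CPM in WT and 0.624 in CR), PCDHB2 (0 and 1.14) and PCDHGB7 (0.296 and 2.2). PCDHGA10 rose from 1.02 to 4.61 CPM. The count and the median thus rest largely on genes near the counting floor. Members share constant exons, so their counts are uncertain. Of 12 keratins 7 were lower and 0 higher (edgeR); beyond KRT7 and KRT8, KRT17 fell from 12.8 ± 2.43 to 0.101 ± 0.0266 CPM and KRT80 from 398 ± 46.9 to 162 ± 9.54 CPM. Without WT replicate 1 or 2, 3 and 1 keratins were higher. These directions were the same under each scaling.

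Members of some cancer-testis antigen families changed in both directions. Of 12 cancer-testis antigens of the MAGE, SSX, CT45 and XAGE families 4 were higher and 6 lower: CT45A1 rose from 0.361 ± 0.0956 to 20.04 ± 2.38 CPM and MAGEA1 from 11.97 ± 7.06 to 94.4 ± 3.98, and MAGEA11 fell from 6.15 ± 3.73 to 0.0199 ± 0.0282. These copies are similar and their counts uncertain. STAG3, a meiotic cohesin subunit, rose from 3.60 ± 0.118 to 228 ± 17.1 CPM (edgeR adjusted p = 9.28e-05), and the imprinted gene PEG10 fell from 564 ± 41.3 to 1.28 ± 0.660 CPM (edgeR adjusted p = 0.000104). Of the 57 genes off in CR, 10 lie on chromosome X (17.5%), against 351 of 10802 genes (3.25%) expressed at the same level in WT; of the 26 genes on in CR, 2 lie there.

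Stretches of neighbouring genes shifted together. Of 658 windows of 50 genes, 26 passed (camera, preset correlation; 15 higher, 11 lower), against at most 0 in 100 random gene orders; with an estimated correlation 0 passed (camera; 8 at an unadjusted p of 0.05). On chromosome 19 from 24.1 to 42.1 Mb, 88.9% of 225 genes were higher in CR (median log2 fold change 0.72), and on chromosome 15 from 82.6 to 100.6 Mb 83% of 100 genes were (median 0.63). On chromosome 20 from 0.3 to 31.6 Mb 85.3% of 150 genes were lower (median -0.89). The larger sign held 50.7% among all genes, but the regions were merged from windows that passed. Their higher shares follow from that choice and are no further support. COX6B1 lies in the first region, FANCI in the second and PCNA and NRSN2 in the third, while AXL and TGFB1 fell within the first. A GC content or length bias is argued against as the whole cause, since the region nearest to 0 kept a median of 0.69 after the correction. Genes with a ZNF symbol numbered 32 of 225 on chromosome 19, 4 of 100 on chromosome 15 and 4 of 150 on chromosome 20. Most genes of these 3 regions were thus not ZNF genes. With so few removed, the medians (0.71, 0.61 and -0.89 without them) could hardly have moved, so they do not test zinc finger clusters. Other, smaller regions passed too and are not described in full. Among them, stretches of chromosome 19 at 18.9 to 24.1, 43.4 to 45.3 and 56.1 to 58.3 Mb were lower in CR. Their medians were -0.42, -0.4 and -0.43, and 18, 21 and 38 of 50 genes in each had a ZNF symbol. Without the ZNF genes these medians were -0.32, -0.49 and -0.57. A copy number difference between the lines may contribute and cannot be told apart from regional regulation, since DNA was not analysed here: genes too weak for the test shifted the same way beyond random lists in 2 of the 3 regions, by 0.83 on chromosome 19 and 0.55 on chromosome 15, but by -0.25, inside the range of -0.35 to 0.34, on chromosome 20.

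The WT libraries differed more than the CR libraries, and the difference followed GC content: the median log2 ratio of replicate 2 to replicate 1 in WT was 0.41 among genes under 42.5% GC and -0.47 among genes over 56.5% GC, compared with 0.04 and -0.04 in CR. Splines in GC content and transcript length took up 26.3% of the variance of the WT log ratio and 6.68% of that of CR. They are argued against as the whole cause, since the WT spread stayed 2.22 times that of CR after their removal, and so is counting noise, since among genes with at least 1000 counts in every library the ratio was 2.81. A difference in culture state or library preparation may remain, and neither was tested.

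The lower interferon, antigen presentation and NF-kB lists in CR were weighed against technical sources. Of the lists fixed as marks of RNA quality, immediate early genes and replication-dependent histones were higher in CR (camera, adjusted p = 0.00223 and 0.00127). Mitochondrially encoded transcripts and ribosomal proteins did not pass (camera, adjusted p = 0.734 and 0.51). Whether RNA handling or selection bears on the 3 lists was not tested. Leukocytes in the WT cultures are argued against as the source of abundant list genes: PTPRC was at 0.273 CPM in WT and 0.384 in CR, while HLA-B was at 1170.0 CPM in WT. The median WT level of the 16 markers was 0.0632 CPM, but they mix lineages, so the median could miss a single lineage. The most abundant markers, ITGAM and CORO1A, fell from 10.2 and 7.94 CPM to 1.03 and 0.69 CPM in CR. For list genes at such low WT levels these values do not settle the question. GC content and length are argued against, since the largest adjusted p of the 3 lists was 1.26e-06 after the correction (camera), as is 1 WT library alone, since the highest list median without either was -0.75. Fibroblast and mesothelial markers were lower beside these lists (camera, adjusted p = 0.0304 and 0.0128, and 0.496 for both with an estimated correlation). The fibroblast median log2 fold change was -1.11 and -1.07 without WT replicate 1 and 2. The 3 immune lists lost their calls with an estimated correlation (camera, adjusted p = 0.37). The estimates were 0.0061 (interferon), -0.016 (antigen presentation) and -0.008 (NF-kB), under the preset 0.01. The loss thus came from the few degrees of freedom of that setting and not from a higher correlation entered in the test. Estimates from 4 libraries are imprecise, so they do not show that these genes vary independently. Whether the WT cultures hold cells of another state was not tested. A lower basal inflammatory state of the CR line is a hypothesis that these values leave open, as is selection of a clone already present in the WT line; profiles of single-cell clones of the WT line and the response of both lines to interferon would test them.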
